A study of Homo sapiens with 8 samples.

How the data were processed

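A massively parallel reporter assay was read in LHCN-M2, an immortalised human skeletal muscle line whose cell type is given in the labels as skeletal muscle myocytes. Per the labels' protocols, DNA fragments carrying variants linked to type 2 diabetes and metabolic traits were cloned beside random barcodes, moved to a lentiviral vector and delivered to the cells by infection, so that the reporters were read from integrated copies. RNA and genomic DNA (gDNA) were isolated together from each of 4 replicates, which gave 8 barcode libraries, 4 of RNA and 4 of gDNA. The gDNA count of a barcode measures how many copies of the reporter the cells carried, and the RNA count how much was transcribed from them. All titles share a term, diff, that the labels do not define, and no other state of the cells was analysed here.

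The authors deposited whole-number counts per barcode and library, without normalization, and a table that pairs each barcode with a fragment and a promoter. Per the labels' protocols, unique molecular identifiers were added in cDNA synthesis and in library PCR. Whether the deposited counts are identifiers or reads is not given in the sources used here, so intervals and errors that rest on counts may not describe independent molecules. The submitters' processing notes name cutadapt without a version. The method that paired barcodes with fragments and the genome build are not given in the sources used here. In each of the 8 libraries, 7117 to 12417 pairs of detected barcodes lay 1 base apart, and the largest ratio of counts within such a pair was 6.67. No library thus held a barcode next to a neighbour at least 10 times as abundant. This does not show that sequencing errors are absent, and the origin of the pairs 1 base apart was not tested. The most common barcode length was 20 bases.

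Counts were joined to the pairing by exact barcode. Of the counts, 14.5% fell on barcodes of the pairing table. The 32623 barcodes paired with both promoters were left out, and 545012 barcodes were used, of which 355322 had a count. The libraries held 11114762 to 16714547 counts, and 1609265 to 2372662 of these were used. The median count of a detected barcode was 4 in each gDNA library and 5 to 6 in the RNA libraries. The number of count columns without a sample was 0.

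Counts were summed over the barcodes of a construct, which is 1 allele of 1 fragment with 1 promoter. A construct entered when at least 10 of its barcodes had gDNA counts in each replicate, which 1324 constructs met and 343 with fewer did not. The median construct had 118 barcodes in its poorest gDNA library, with a range of 10 to 1287, and a median of 4165 gDNA and 4584 RNA counts over the 4 libraries of a kind. Activity is log2 of RNA over gDNA after TMM scaling (trimmed mean of M values), so 0 is the typical construct of this library and not the absence of transcription. No fragment was named as a negative control. Per-replicate ratios used a prior of 0.5 counts.

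The tests were edgeR's quasi-likelihood tests, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, called the replicate test in the text. They were fitted to all 8 libraries with terms for molecule, and for the interaction of molecule with allele, promoter, tile, or allele and promoter. A library's size and scaling factor were shared by its columns in such fits. A called item passed the threshold. The replicates share 1 pool of barcodes, so the spread between replicates leaves out the spread between barcodes. For that reason, the same ratios were tested with errors from the spread between barcodes, as a linearised ratio, called the barcode test. It sums each barcode over the 4 replicates and so leaves out the spread between replicates. Neither test holds both kinds of spread. The barcode test was chosen after the data were seen. An SE in the text is that of the replicate test unless named as over barcodes. A Welch test between the barcodes of both alleles had been planned. Between 2 random equal subsets of the barcodes of 1 construct, over 1284 constructs, the barcode test gave 6.62% of p-values under 0.05 and 4 calls, and the Welch test in 1180 constructs gave 4.83% and 0 calls.

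Replicate numbers pair the libraries, because RNA and gDNA of a number were isolated from 1 culture per the labels' protocols. Across constructs, the deviations of same-numbered RNA and gDNA libraries from their group means correlated at 0.28, -0.11, 0.36 and 0.19 for replicates 1 to 4. The fits had no replicate block, and blocked fits were alternatives. Other alternatives set beforehand were DESeq2, library totals without TMM, limma on log2 ratios with a pseudocount of 1 CPM, barcode minimums of 1 and 30, only barcodes with gDNA in all replicates, leaving out the barcode of highest RNA, the median over barcodes, and leaving out each replicate. The median over barcodes and the Welch test used log2 ratios of single barcodes with a pseudocount of 1 count. With median counts of 4 to 6 per detected barcode, such ratios are coarse and drawn toward 0. The labels do not say whether the replicates were separate infections, so the p-values measure the spread between these 4 cultures.

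The fits were tested on simulated counts. For activity, a log2 change of 0.3 was recovered in 80% and of 0.6 in 99% of 100 constructs each. For the allelic test the shares were 65% and 98%, for the promoter test 58% and 99%, and for the interaction of allele and promoter 26.1% and 91.2%. These simulations held no spread between barcodes.

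The items to name were the 10 highest and 5 lowest called constructs with 1 sign in all replicates, and 20 allelic calls spread over the 6 combinations of promoter and tile, up to 3 from each and the rest by adjusted p. This rule was written before the data were examined. Some items that it picks are not reported here and were not replaced. Tile and promoter examples were chosen after their values were seen. Positions are those in the deposited fragment names, which state no build. Gene names come from the GRCh38.p14 RefSeq table, which gives gene spans without strand or exons. All 14 well-known variants listed beforehand lay inside their known gene in that table, against 1 and 2 of 14 after shifting positions down or up by 250 kb. Of the 327 variants, 225 lay inside a protein-coding gene. Fragments named by interval were not assigned genes, since 1 of them lay beyond the end of the last gene listed for its chromosome. Their positions may thus be on another build than those of the variants.

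Fragment sequences were not used here, so the planned tests of 28 motifs, of GC content and of distance to transcription starts were not run. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table.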

Results

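Regulatory activity was read in LHCN-M2 human skeletal muscle cells from a library that listed 860 fragment alleles, 788 of them carrying 1 allele of 327 variants. Activity was tested for 682 fragment alleles, which covered 273 variants, in reporters with 1 of 2 promoters. The promoters were SCP1, a synthetic super core promoter, and that of MYBPC2, the gene of fast-type myosin binding protein C of skeletal muscle. A further 61 fragments were named by a position only and 11 by an interval and strand. Most variants lay in fragments named without a shift, called centre tiles here, and 38 and 41 variants also or only had fragments named left and right. The 4 gDNA libraries held 11114762 to 13594556 counts, of which 14.5% to 15.0% were used. The 4 RNA libraries held 13680004 to 16714547, of which 13.6% to 14.8% were used. Summed over constructs, gDNA libraries correlated with each other at r = 0.995 to 0.997 and RNA libraries at 0.989 to 0.996. The log2 ratios of RNA over gDNA correlated at 0.713 to 0.785 between replicates. These correlations are across constructs, which are not independent replicates.

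The first comparison asked which fragments drove more or less RNA than the typical construct. Fragments at 1 variant each in ZNF329, a zinc finger gene, and in CDH13, which encodes T-cadherin, a receptor of adiponectin, were among the highest. Fragments at 1 variant each in SLC2A4, the gene of the insulin-responsive glucose transporter GLUT4, in AKAP10, which encodes an anchor of protein kinase A, in MAU2 and in HTR1F were low with either promoter and allele. Of 1324 constructs, 247 were called higher and 278 lower than the typical construct, and 178 of the higher and 174 of the lower were also called by the barcode test. These calls partly followed the promoter, with 186 higher and 77 lower for MYBPC2 and 61 higher and 201 lower for SCP1. Fits within each promoter called 136 higher and 151 lower for MYBPC2 and 142 higher and 140 lower for SCP1. Effects were small, with 24 constructs above 0.5 and 66 below -0.5 on the log2 scale.

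The SCP1 construct of rs34003091 (chromosome 19, position 58150887, in ZNF329) was highest, at 0.88 ± 0.29 (log2, SD, n = 4) with the alternate and 0.72 ± 0.21 with the reference allele. The reference allele of rs4782722 (chromosome 16, position 82638560, in CDH13) reached 0.85 ± 0.18 with SCP1, the best supported of these with 478 barcodes. At these 2 variants and at rs2549805 in ERAP1, an aminopeptidase of the endoplasmic reticulum, all 4 constructs of allele and promoter were called higher by both tests. With MYBPC2, 3 alternate alleles in MARCHF10, a ubiquitin ligase gene, were among the highest. They were rs11867290 at 0.77 ± 0.23, rs2286567 at 0.77 ± 0.25 and rs1968118 at 0.74 ± 0.09, at positions 62791047, 62750299 and 62771630 of chromosome 17. The interval fragment that starts at position 101618660 of chromosome 2 reached 0.75 ± 0.24 with MYBPC2. The reference allele of rs6813 (chromosome 17, position 19905132, in AKAP10) reached 0.69 ± 0.24 with MYBPC2. Some of these rested on few barcodes. The barcode test did not call rs11867290 (adjusted p = 0.0904), and with the median over barcodes rs1968118 fell to -0.19 and rs6813 to -0.57.

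The 5 lowest constructs all carried SCP1. The alternate allele of rs11085261 in MAU2 (chromosome 19, position 19351797) was lowest at -1.31 ± 0.25 (log2, SD, n = 4). It rested on 15 barcodes in its poorest gDNA library, and on 181 gDNA and 80 RNA counts in all. The reference allele of the left tile of rs73872719 in ZBTB38, a zinc finger gene (chromosome 3, position 141416133), was at -1.23 ± 0.12. The alternate alleles of rs59791349 in EYA2 (chromosome 20, position 46975185) and rs12616899 in UBXN2A (chromosome 2, position 23942365) were at -1.20 ± 0.14 and -1.15 ± 0.21. That of rs12616899 had 25 barcodes in its poorest gDNA library. The reference allele of rs6457816 in PPARD, a nuclear receptor gene (chromosome 6, position 35395071), was at -1.05 ± 0.10. The barcode test called 4 of the 5, and not rs59791349 (adjusted p = 0.286), whose error over barcodes was 0.78. At 6 variants all 4 constructs were called lower by both tests. These included rs117643180 in SLC2A4 (log2 -1.01 to -0.52), rs203449 in AKAP10 (-0.86 to -0.57) and rs10402661 in MAU2 (-0.78 to -0.44). The others were rs2082226 in HTR1F, a serotonin receptor gene (-0.81 to -0.39), rs181704186 nearest to DUSP23 (-0.67 to -0.35) and rs56151256 in LINGO1 (-0.43 to -0.22).

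**Figure D1:**
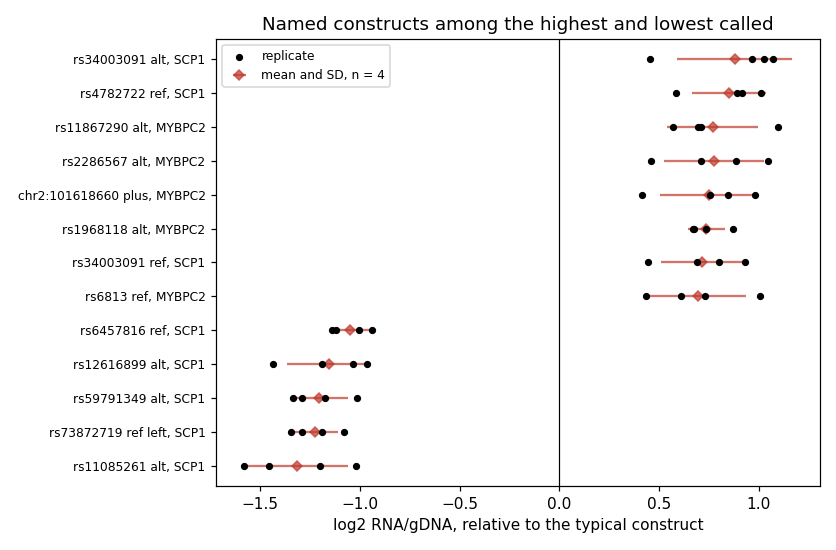
Log2 RNA over gDNA (horizontal axis, 0 is the typical construct) of 8 constructs among the highest called and of the 5 lowest, with the 4 replicates as points and the mean and SD as a diamond and bar. The highest means are near 0.88 and the lowest near -1.31, and all replicates of a construct lie on 1 side of 0.

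By kind of fragment, interval fragments with MYBPC2 had a mean of 0.22 ± 0.27 (log2, SD, n = 10 fragments), above the 0.01 ± 0.19 of 45 position-only fragments (two-sided permutation test, p = 0.00558, adjusted p = 0.0446 over 8 tests). These 8 tests were not part of the plan set beforehand. The 10 fragments include 1 interval in both orientations, so they are not all independent. None of the other 7 comparisons passed, such as variants inside against outside protein-coding genes with SCP1 (adjusted p = 0.0554) and with MYBPC2 (adjusted p = 0.642). Among 10 genes that held 5 or more variants, RGS12, a regulator of G protein signalling, had 9 of 12 variants with a construct higher by both tests against 94 of 261 others (Fisher's exact test, p = 0.0115, adjusted p = 0.229 over 20 tests). MARCHF10 had 10 of 15 (adjusted p = 0.261). No gene passed after adjustment.

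The second comparison set the promoters side by side. By summed counts, fragments were more active with the MYBPC2 promoter, relative to the typical construct of the whole library, than with SCP1. The median difference over 642 fragments was 0.17 on the log2 scale, a 1.12-fold difference, and 480 fragments lay above 0. In 212 fragments activity was higher with MYBPC2 and in 17 it was lower. The barcode test called 138 and 4 of these. With the median over barcodes in place of summed counts, the median difference was 0.07 and 0 fragments were called (lowest adjusted p = 0.0555). MYBPC2 constructs held 37.6% to 39.8% of gDNA counts and 39.7% to 44.2% of RNA counts, a rise of 2.81 ± 1.36 percentage points (SD, n = 4 pairs, positive in every pair, exact paired permutation test, p = 0.125, the smallest that 4 pairs allow). Activity with the promoters was correlated across fragments (Pearson r = 0.531, Spearman rho = 0.443, permutation p = 1e-05 for each, the smallest that the permutations give, adjusted p = 1.67e-05 over 5 correlations). Alleles and tiles of 1 variant share sequence, so the fragments are not independent, while these p-values treat them as if they were. The median difference was 0.26, 0.17, 0.12 and 0.09 in replicates 1 to 4, and the calls fell to 125 without replicate 1 and to 102 without replicate 2.

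Among fragments that were low with SCP1, differences of 1.03 ± 0.12 and 1.01 ± 0.11 (log2, SE of the replicate test) were found for the alternate allele of rs4689398 in WFS1, the gene of Wolfram syndrome, and the reference allele of rs17025236 nearest to HTR1F. The reference allele of rs6457816 in PPARD differed by 0.84 ± 0.12. Other fragments were closer to the typical construct with SCP1 and high with MYBPC2. They included the reference allele of rs6813 in AKAP10 (-0.20 with SCP1 and 0.69 with MYBPC2, difference 0.90 ± 0.18) and the alternate allele of rs1968118 in MARCHF10 (-0.06 and 0.74, difference 0.79 ± 0.12). Both tests called each of these differences, but with the median over barcodes the last 2 turned to -0.20 and -0.07. Those of rs4689398, rs17025236 and rs6457816 were then 0.77, 0.18 and 0.00. At few counts per barcode these medians are coarse. A value near 0 then cannot tell a minority of high barcodes from low counts. Both tests called 4 fragments lower with MYBPC2. They included the left tile of the alternate allele of rs1635852 in JAZF1 (-0.62 ± 0.12) and the interval fragment that starts at position 16035285 of chromosome 12 (-0.58 ± 0.11). The others were the reference alleles of rs229527 in C1QTNF6 (-0.31 ± 0.10) and rs4782722 in CDH13 (-0.24 ± 0.09).

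**Figure D2:**
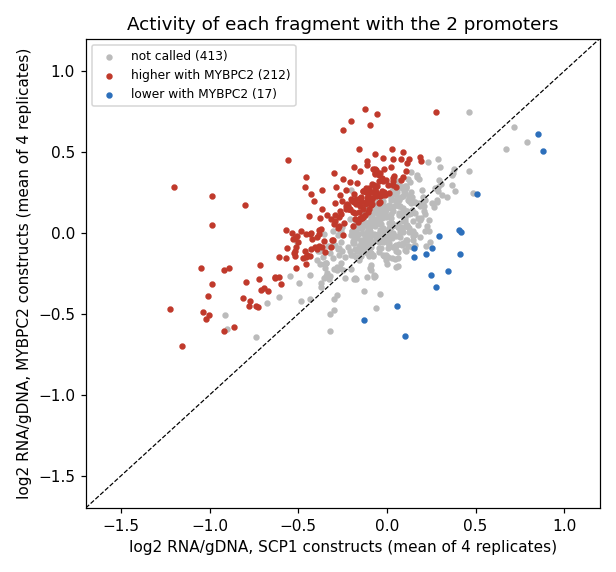
Mean log2 RNA over gDNA of 642 fragments (points) with SCP1 (horizontal axis) and with MYBPC2 (vertical axis), with the dashed line at equal values. The 212 fragments called higher with MYBPC2 lie above the line and the 17 called lower below it.

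The third comparison asked how activity depended on which stretch around a variant was placed in the reporter. The right tile of rs12616899 in UBXN2A was more active than the centre tile with both alleles and both promoters. The difference was 1.14 ± 0.11 and 1.10 ± 0.15 with SCP1 for the reference and alternate alleles and 0.74 ± 0.11 and 0.85 ± 0.12 with MYBPC2 (log2, SE of the replicate test). In the same order, the centre tile was at -1.01, -1.15, -0.50 and -0.70 and the right tile at 0.13, -0.06, 0.23 and 0.14. The difference thus lay mainly in a low centre tile. The right tile of rs9822268 in APEH, which encodes an acylpeptide hydrolase (chromosome 3, position 49682296), was less active than the centre tile in the same 4 combinations. The difference was -1.07 ± 0.10 and -1.01 ± 0.09 with SCP1 and -0.51 ± 0.08 and -0.66 ± 0.09 with MYBPC2. The left tile of rs73872719 in ZBTB38 was lower than its centre tile. The difference was -1.32 ± 0.10 and -0.84 ± 0.11 with SCP1 and -0.54 ± 0.09 and -0.43 ± 0.08 with MYBPC2. Both tests called each of these differences, except the last, which the barcode test did not call (adjusted p = 0.105). The SE over barcodes, in the same order, was 0.20, 0.23, 0.17 and 0.19 for rs12616899. It was 0.10, 0.12, 0.09 and 0.11 for rs9822268 and 0.35, 0.12, 0.15 and 0.19 for rs73872719.

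Over 21 variants, 25 of 80 left and centre pairs were called, 7 with the left tile higher and 18 lower. Of 79 right and centre pairs, 27 were called, 16 higher and 11 lower. Of 75 left and right pairs from 20 variants, 31 were called, 10 higher and 21 lower. The barcode test left 0 higher and 9 lower, 8 and 7, and 5 and 6 of these, and the paired fits with a replicate block called 42, 53 and 54.

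**Figure D3:**
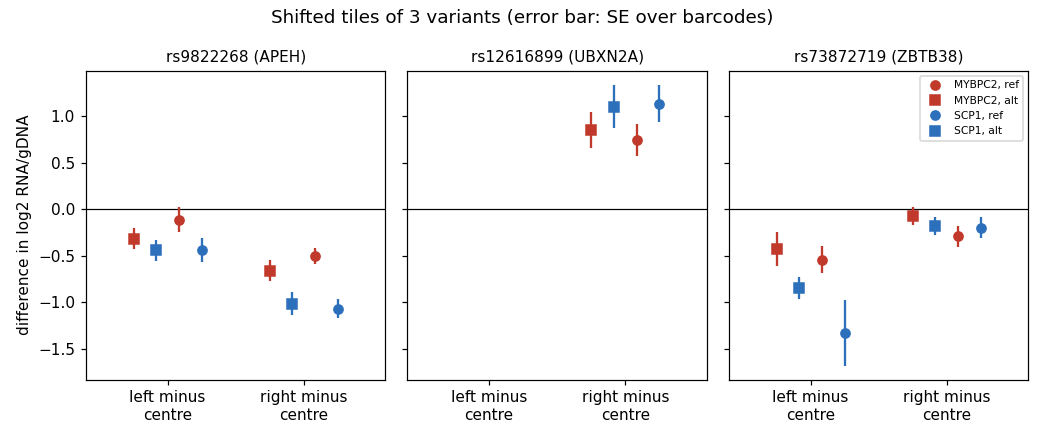
Difference in log2 RNA over gDNA between a shifted and the centre tile (vertical axis) for 3 variants, by allele (circle, reference; square, alternate) and promoter (colour), with bars of 1 SE over barcodes. All 4 combinations lie above 0 for the right tile of rs12616899, which had no left and centre pair, and below 0 for the right tile of rs9822268 and the left tile of rs73872719.

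The fourth comparison asked whether the alleles of a variant differed in activity. In 571 pairs of alleles, from 251 variants, the replicate test called 47. The alternate allele was higher in 24 and lower in 23, and all 47 had 1 sign in 4 of 4 replicates. The signs are not separate support, since the same replicates gave the calls and share 1 pool of barcodes. Random subsets of the barcodes of 1 and the same allele gave calls as well. Of 520 pairs with at least 20 barcodes per allele, 35 were called between the alleles with all barcodes, while 2 random equal subsets of the reference allele's own barcodes, tested as if they were alleles, gave 51.4 ± 9.86 calls (SD, 20 draws). Subsets drawn in the same way from different alleles gave 60.3 ± 6.93. The barcode test called 0 pairs, with 53 of 571 at an unadjusted p under 0.05 and a lowest adjusted p of 0.171. The test between the barcodes' own log2 ratios also called 0, with 33 of 552 at an unadjusted p under 0.05. DESeq2, which like edgeR reads the replicates, called 60. The values that follow therefore describe the barcodes in this pool, and a difference between alleles was not detectable against the spread between barcodes after adjustment.

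The largest allelic difference was at rs59791349 in EYA2, a coactivator of muscle development, where the alternate T allele was lower than the reference C allele with SCP1 by -1.37 ± 0.11 (log2, SE; adjusted p = 1.47e-11), with an SE over barcodes of 0.80. With MYBPC2 the difference was -0.08. The alternate allele was higher at the right tile of rs117826138 nearest to SLC5A1 (0.83 ± 0.12) and at rs1968118 in MARCHF10 (0.77 ± 0.14), both with MYBPC2. At rs7903146 in TCF7L2, the gene of a transcription factor of Wnt signalling at a type 2 diabetes locus (chromosome 10, position 112998590), the T allele was higher than the C allele by 0.37 ± 0.09 with MYBPC2 (adjusted p = 0.00722; SE over barcodes 0.16) and differed by -0.07 with SCP1. At the right tile of rs647968 nearest to CITED2 (chromosome 6, position 139932383) the G allele was lower with both promoters, by -0.48 ± 0.10 with MYBPC2 and -0.33 ± 0.09 with SCP1, the 1 case called with both.

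Other alternate alleles called higher were those of rs17554326 in WARS1 (0.57) and rs12876143 in ATP11A (0.46) with MYBPC2, and of the left tiles of rs73872719 in ZBTB38 (0.45) and rs1535883 in SIRPG (0.41) with SCP1. Lower alternate alleles with SCP1 were those of rs4076457 in LINGO1 (-0.42), rs6829279 in RGS12 (-0.36), the left tile of rs1716165 in MPHOSPH9 (-0.62) and the right tile of rs921068 (-0.45). With MYBPC2 they were those of rs10771371 nearest to KLHL42 (-0.51), rs4689391 in WFS1 (-0.47), rs2323413 nearest to GYPE (-0.42) and the right tile of rs2870463 nearest to CTRB1 (-0.38). The deposited names place rs921068 at position 42979841 of chromosome 2, rs2323413 at position 143947855, rs4689391 at position 6278722 and rs6829279 at position 3298356 of chromosome 4, and rs10771371 at position 27807540 and rs1716165 at position 123164334 of chromosome 12. Further positions were those of rs12876143 at position 112711977 of chromosome 13, rs17554326 at position 100376040 of chromosome 14, rs4076457 at position 77714871 of chromosome 15 and rs2870463 at position 75216819 of chromosome 16. The remaining positions were those of rs1968118 at position 62771630 of chromosome 17, rs1535883 at position 1632173 of chromosome 20 and rs117826138 at position 32002162 of chromosome 22. The protein-coding gene nearest to rs921068 was LOC107985876. With the median over barcodes rs73872719 was at -0.07. Fits with the replicate block called 118 pairs, and the calls fell to 22 without replicate 1, 8 without replicate 2 and 25 without replicate 4.

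**Figure D4:**
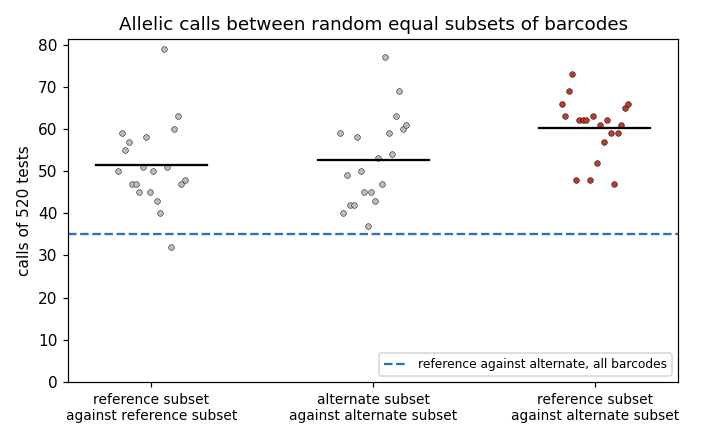
Number of calls in 520 allelic tests (vertical axis) when random equal subsets of the barcodes of 1 allele, or of both alleles, are compared, with 20 draws as points, their mean as a bar and the dashed line at the 35 calls between alleles with all barcodes. Subsets of the reference allele average 51.4 calls and subsets of different alleles 60.3.

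The fifth comparison asked whether allelic differences depended on the promoter. In 16 of 275 variants and tiles the difference between alleles differed between promoters. The largest were those of rs59791349 in EYA2 (1.29 ± 0.18, MYBPC2 minus SCP1, log2, SE), rs11867290 in MARCHF10 (0.90 ± 0.21) and rs117826138 nearest to SLC5A1 (0.78 ± 0.18). In 10 of the 16 every replicate had opposite signs with the promoters, in the same replicates that gave the calls. The barcode test called 0, with 21 at an unadjusted p under 0.05. Across the 275 variants and tiles, allelic differences with the promoters were not correlated (Pearson r = 0.0305, permutation p = 0.611, adjusted p = 0.764; Spearman rho = 0.0129, permutation p = 0.832, adjusted p = 0.971). Among the 137 with at least 100 barcodes for all 4 constructs r was -0.0233 (permutation p = 0.788, adjusted p = 0.788). Of 45 allelic calls tested with the other promoter, 27 had the same sign there (exact binomial test, p = 0.233). The right tile of rs647968, called with both promoters, entered 2 times, so the 45 are not all independent. The alleles of a variant were alike in level, with r = 0.712 and rho = 0.626 between alternate and reference alleles with SCP1 over 287 pairs and r = 0.637 and rho = 0.618 with MYBPC2 over 284 (permutation p = 1e-05 for each, the smallest they give, adjusted p = 1.67e-05). Tiles of 1 variant enter as separate pairs, so the pairs are not all independent. The replicate block called 33 interactions, and leaving out replicate 1, 2 or 4 left 5, 7 or 4.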

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

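The test of sequencing errors among unpaired barcodes and the comparison with subsets of different alleles were chosen after their results were seen, and the promoter medians without the barcode of highest RNA and with the median over barcodes were added after seeing the data. The largest body of signal outside the comparisons was the 85.5% of counts on barcodes absent from the pairing table. Their RNA over gDNA ratio was 1.01 to 1.10 times that of the paired barcodes. Sequencing errors of paired barcodes would leave low counts, but an unpaired barcode had 1.43 times the mean gDNA count of a paired one (SD 0.030 over 4 gDNA libraries), which argues against errors as the source. A search for unpaired barcodes next to a far more abundant paired one was void, because in none of the 8 libraries did the counts of detected barcodes 1 base apart differ by 10 times or more. Reporters whose barcode was never paired may account for these counts, which was not tested, and no biological explanation was tested.

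A second pattern is the set of 47 allelic calls. Of the 35 splits of the 8 libraries, 1 gave as many, the real one, and the highest of the others gave 0. Every other split mixed RNA and gDNA libraries within a group, so the difference between RNA and gDNA added to the spread there. The splits thus could not decide whether these calls arose by chance. The splits that part all 4 pairs number 8, too few for a share under 0.05. The real one of these gave 47 and the highest other 0, and both limits hold for the other counts of calls below. The spread between barcodes of 1 allele may account for most of the calls. Random equal subsets of the reference allele's own barcodes gave 147% of the calls between alleles with all barcodes, and 85.2% of the calls between like subsets of different alleles. The excess between different alleles was not tested, since the draws reuse the same barcodes. Single calls may still be true allelic effects, and that stays open at this number of barcodes.

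Another pattern is the higher activity of MYBPC2 constructs. The 229 promoter calls were matched by 1 of 35 splits, the real one, with 0 as the highest other. A single dominant barcode per construct is unlikely as the source, because the median difference was 0.171 without the barcode of highest RNA in each construct. With the median over barcodes it fell to 0.0715 with 0 calls, so a minority of high barcodes stays open as a source of part of it. The pseudocount of 1 at few counts per barcode also draws this median toward 0, by an amount that was not measured. A biological difference between the promoters in these cells was not tested and stays open. Differences in how the SCP1 and MYBPC2 pools were built or paired were not tested and stay open.

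The 16 variants and tiles whose allelic difference depended on the promoter were flagged as differences between groups, and 1 of 35 splits gave as many, the real one, with 0 as the highest other. The barcode test called 0 of 275 (lowest adjusted p = 0.558), so a dependence on the promoter was not detectable against the spread between barcodes. Among the variants named by the rule for an allelic difference, the flagged ones were rs59791349 (1.29), rs117826138 (0.78), rs921068 (0.77), rs1968118 (0.70), rs6829279 (0.51) and rs7903146 (0.44), as MYBPC2 minus SCP1 on the log2 scale. The 16 also hold variants named elsewhere in the text, such as rs11867290 (0.90). The 525 activity calls were likewise matched by 1 of 35 splits, the real one, with 0 as the highest other.

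A far replicate was found in 4 of 40 groups of 4 values. The rate by chance in such groups was not measured, so 4 is not read as an excess. The activity of the alternate allele of rs34003091 with SCP1 was 0.45 in 1 replicate and 0.97 to 1.07 in the others. The allelic difference of rs1968118 with MYBPC2 was 1.11 in 1 replicate against 0.66 to 0.67, and that of rs7903146 was 0.18 against 0.42 to 0.45. The share of counts used was 14.5% in gDNA replicate 3 and 14.9% to 15.0% in the other gDNA libraries.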

How the results depend on the processing

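The barcode errors, the fits within each promoter and of both promoters together, the promoter fits without the barcode of highest RNA and with the median over barcodes, and the interaction fit without TMM were chosen after seeing the data. Activity calls ranged from 366 to 639 over the alternatives run, which tested 1153 to 1628 constructs, against 525 of 1324 in the main fit. Of the 525, 296 were shared with the median over barcodes, 352 with the barcode errors and 414 with fits within each promoter. The allelic count moved to 118 with the replicate block, 182 with limma on log2 ratios, 87 of 709 pairs without a barcode minimum, 28 of 492 with at least 30 barcodes, and 15 of 275 variants and tiles with both promoters together, a different set of tests. The median over barcodes gave 0 promoter calls and a promoter median of 0.071. The allelic count was 0 with the median over barcodes, 0 with barcodes as the unit and 0 with barcode errors. The replicate block, which pairs RNA and gDNA of a culture, also gave 33 allele and promoter interactions, and 42, 53 and 54 tile calls (left over centre, right over centre, left over right). It kept every call of the unblocked fits. Barcode errors gave 152 promoter calls, 0 interactions, and 9, 15 and 11 tile calls.

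Without 1 replicate, the counts ranged from 366 to 505 for activity, 8 to 51 for alleles, 102 to 251 for promoters, 4 to 19 for interactions, and 19 to 23, 22 to 29 and 20 to 30 for tiles, and the promoter median from 0.13 to 0.19. Fewer libraries were fitted in these. The median over barcodes reversed the activity of rs1968118 (-0.19) and rs6813 (-0.57) and the allelic difference of rs73872719 (-0.065), and with barcodes as the unit this difference was -0.00094. The cause was not tested. Of 18 named allelic differences, barcode errors ended all 18 calls and turned 0. Leaving out the barcode of highest RNA ended 2 of these 18 calls and 2 of the 13 named activity calls. More was lost among all calls, where 29 of the 47 allelic and 439 of the 525 activity calls remained. That fit called 37 allelic pairs and 512 constructs. The planned motif, GC and transcription start tests were not run. The median SE over barcodes was 0.14 over all allelic pairs and 0.24 over the called ones, against 0.10 and 0.11 in the replicate test.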

Other observations

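The tests of genes in this part were chosen after the data were seen. The 1 interval placed in both orientations, at position 80992942 of chromosome 8, was at 0.28 ± 0.06 (log2, SE) in the plus orientation and 0.05 ± 0.06 in the minus orientation with MYBPC2, and at 0.05 ± 0.06 and -0.14 ± 0.06 with SCP1. The difference between orientations was not tested. The interval that starts at position 3762591 of chromosome 19 was higher with both promoters, at 0.39 ± 0.08 with MYBPC2 and 0.47 ± 0.07 with SCP1, and both tests called it. The interval that starts at position 16035285 of chromosome 12 was lower with MYBPC2 (-0.24 ± 0.08) and higher with SCP1 (0.35 ± 0.07).

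By gene, ERAP1 had 11 of 36 constructs higher and 1 lower by both tests, and RGS12 15 of 46 higher and 2 lower. ACTN3, the gene of the fast-fibre alpha-actinin of skeletal muscle, had 4 of 39 higher and 10 lower, and AKAP10 4 of 45 higher and 11 lower. None of the 20 tests of genes passed after adjustment (lowest adjusted p = 0.229). Constructs of 1 variant share sequence, so these counts are not of independent constructs.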
